A study of Mus musculus with 23 samples.

How the data were processed

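Smart-seq2 RNA sequencing of sorted Tregs gave 23 libraries in 6 groups, DN, SP, DP, LN_103N and LN_103P with 4 libraries each and SPLN with 3. Group names and sort labels were taken from the labels, which give the numbers 861, 869, 943 and 946 in each group of 4 but do not say whether these are separate animals. The p-values therefore measure the spread between samples and nothing beyond it.

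The authors estimated counts per gene with RSEM 1.2.12 and Bowtie 1.0.1 against mm9, per the submitters' processing notes, and deposited these estimated counts for 23224 genes. The values were not whole numbers in 22.6 to 31.1% of a library's entries, and 1619 genes were at 0 in every library. The authors also deposited a normalized signal for 22484 genes. In each library that signal was the estimated count multiplied by 1 factor for all genes, inversely proportional to the upper quartile of the genes seen in any library (190 to 395.2 counts), with the ratio equal to within 5.33e-15 of itself. Of the 740 genes found in the counts alone, 626 had microRNA or Ncrna symbols. The annotation and the read filters are not stated. No coordinates are given because the reference annotation at hand is of another build than mm9.

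Counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Total counts per library were 8397241 to 14412601. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15, smallest group size 1, since SPLN is 1 sample), which left 16186 genes. Library sizes were scaled by TMM. The 3 SPLN libraries carry the same number, had a chi-square per degree of freedom of 1.196 to 1.498 among themselves over genes with at least 20 counts (33.9 to 190 for the 30 other pairs within groups) and correlations of 0.9958 to 0.9964 (0.7693 to 0.9214 for the others). They were summed, so that the fit held 21 samples. All groups shared 1 quasi-likelihood fit with no block. The labels do not say that a number marks 1 mouse, so the numbers were not treated as pairs, and the block on the number is an alternative. Residual correlations between libraries of the same number over pairs of groups were all under 0.1 (-0.0422 to 0.0902). Their small size does not exclude pairing, since their mean was higher within numbers than between them in all 10 pairs of groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Levels are the CPM that edgeR computes from the TMM-scaled library size, as mean ± SD. For each called gene given with a value, all 4 libraries of the higher group lay above all 4 of the lower group.

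A fold change against a group with no counts is a lower bound from a floor of 3 counts over the group. A group with 1 to 3 counts has its ratio with a 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The sort was not independent of Itgae and Klrg1, whose proteins defined the groups.

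The 24 gene lists, with 338 symbols counted by list, were fixed before the data were examined. Of these symbols 333 were found as written, 4 under an older symbol and 1 not at all, and 315 were tested. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01, and adjustment over the 24 lists of a comparison. The test with an estimated correlation is given beside it. Both compare the members of a list with all other genes, so that higher and lower are relative to those. Of 61 list calls, 21 held with an estimated correlation, and in none of the 61 did the median, mean and test differ in sign. They did in 28 of the 131 tests that did not pass. Members past the threshold were counted over all genes and adjusted over the list alone. Several lists share genes, and Tregs themselves express some genes on the marker lists.

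Named genes followed a rule fixed before the data were examined. Itgae, Klrg1, Foxp3 and Il1rl1 were named in every comparison. Called genes with a symbol, at least 10 CPM in the higher group and no overlap between the groups' libraries were named by the largest rise or fall, up to 8 each way in the comparisons of CD103 or KLRG1 and 5 each way in those of the tags. From each list with at least 2 called members, or called as a set, up to 3 members with the smallest adjusted p were added. In comparisons with 7 or fewer calls the remaining genes were named after their values were seen. The text gives part of the genes the rule selects.

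On simulated counts with 50 changed genes per size, the fit of DP against DN recovered 16, 74, 84 and 98% of 2-, 4-, 8- and 16-fold changes among 15866 genes, with 0 false calls. The fit of DN against LN_103N recovered 12, 64, 86 and 92% among 15884 genes, with 4 false calls (3.05% of its calls). Changed genes were drawn from those with a mean of at least 10 CPM. Counts were simulated from the model of the fit with its estimated dispersions. These shares therefore need not hold for the real counts or for less abundant genes.

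Alternatives fixed before the data were examined were a block on the number, DESeq2 size factors or total counts as the scale, DESeq2 1.42.0, limma voom with sample quality weights, limma on log2 of the normalized signal plus a pseudocount of 1, no filter, a filter of 5 CPM in 4 libraries, a fit of only the groups compared, at least a 2-fold change, SPLN libraries as separate samples, and leaving out each library in turn. Removing Rn45s and leaving out the 4 libraries of lowest voom quality weight (DN 861, LN_103N 946, DP 869 and SP 869) were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No per-sample column of the deposited tables was left unused.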

Results

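RNA sequencing measured transcripts in regulatory T cells (Tregs) sorted from C57Bl/6 mice. The mice carry a Cre-activated LSL-Kras G12D allele, floxed p53 alleles and a Foxp3RFP reporter of the Treg transcription factor. Cells had been sorted by surface CD103, the integrin alpha E chain encoded by Itgae, and by KLRG1, an inhibitory receptor of differentiated lymphocytes encoded by Klrg1. The 23 libraries fell into 6 groups. DN (CD103-KLRG1-), SP (CD103+KLRG1-) and DP (CD103+KLRG1+) had no tissue tag in their titles and held 4 libraries each. LN_103N (CD103-KLRG1-) and LN_103P (CD103+KLRG1-) also held 4 libraries each, and SPLN (CD103-KLRG1-) held 3 libraries that all carried the number 861. The labels do not spell out the tags LN and SPLN, so they are used here as names only. Total counts per library ranged from 8397241 to 14412601, and 10.65 to 34.53% of them came from Rn45s, the ribosomal RNA precursor. At least 1 count was present for 12075 to 14329 genes in the 20 libraries of the groups of 4 and for 16434 to 17022 genes in the SPLN libraries. Levels are library-scaled counts (CPM). The 3 SPLN libraries differed little beyond counting error (chi-square per degree of freedom 1.196 to 1.498, against 33.9 to 190 for pairs within the other groups) and were summed into 1 sample.

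**Figure D1:**
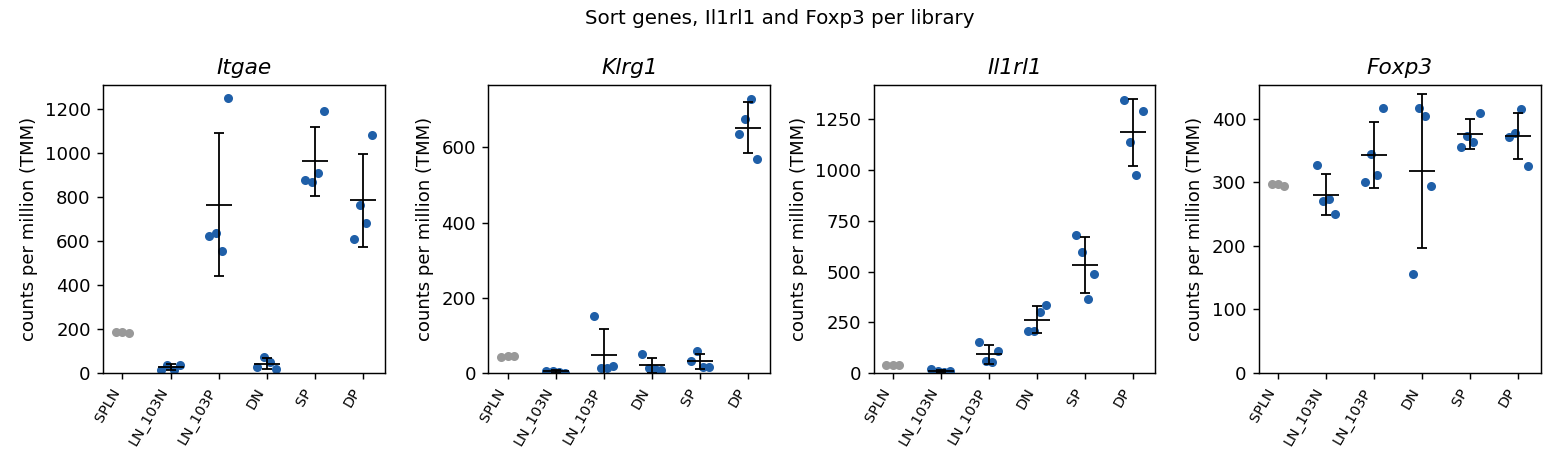
Library-scaled counts (CPM, vertical axes) of Itgae, Klrg1, Il1rl1 and Foxp3 in each library, by group on the horizontal axes, with points for libraries, bars for the mean and SD of 4 libraries, and SPLN in grey without a bar. Itgae averaged 783 CPM in DP, 960 in SP and 763 in LN_103P against 42.4 in DN and 26.1 in LN_103N, and Klrg1 averaged 653 CPM in DP.

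The comparison of DP with DN asked how Tregs that carry both surface proteins differ from those that carry neither, in a series on IL-33 signalling and Treg diversity. Il1rl1, which encodes the IL-33 receptor ST2, was higher in DP, at 1187 ± 166 CPM against 263 ± 66.0 CPM in DN (SD, n = 4 each; log2 fold change 2.18 ± 0.36 SE, adjusted p = 0.00937). Itgae and Klrg1 followed the sort labels, with log2 fold changes of 4.20 ± 0.41 (adjusted p = 9.02e-06) and 5.01 ± 0.85 (adjusted p = 0.0102). Laptm4b, a lysosomal membrane protein gene, was higher by 1.88 ± 0.32. Tcf7, which encodes the transcription factor TCF-1 of naive and memory T cells, was lower in DP, at 19.6 ± 8.25 CPM against 116 ± 24.9 CPM (-2.57 ± 0.30, adjusted p = 0.000128). The tetraspanin gene Cd9 (-6.65 ± 0.82) and Cxcr3, a chemokine receptor of type 1 responses (-2.00 ± 0.33), were lower as well. Foxp3 was at 373 ± 36.4 CPM in DP and 318 ± 121 CPM in DN (0.23 ± 0.22, adjusted p = 0.808). DN 861 was lowest in DN for Foxp3, at 155.6 CPM against 294.7 to 417.2 CPM. It was also lowest for Cd4, at 272.2 CPM against 551.6 to 713.4 CPM.

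The effector and tissue Treg programme, like all lists fixed before the data were examined, was tested as a set and was higher in DP (adjusted p = 1.69e-06 with the preset inter-gene correlation, and adjusted p = 0.0211 with an estimated correlation). Il1rl1 was the 1 of its 16 measured members past the test over all genes, and 5 passed adjusted over the list alone. Areg, which encodes the tissue repair factor amphiregulin, had a log2 fold change of 1.54 and did not pass over all genes (adjusted p = 0.0722). The naive and central T cell list was lower in DP (adjusted p = 1.21e-06, and 0.038 with an estimated correlation), with 2 of 15 members past the test, Tcf7 among them, and 5 adjusted over the list alone. The markers of CD8 T and NK cells were lower in DP (adjusted p = 9.35e-05, and 0.0441 with an estimated correlation), with 0 of 11 members past the test and 5 adjusted over the list alone. With an estimated correlation that call ended with the replicate number as a block (adjusted p = 0.0836) and without the 4 libraries of lowest quality weight (adjusted p = 0.0644), as the naive and central T cell call did in the latter (adjusted p = 0.0644). The summed levels of these markers were 137 ± 51.4 CPM in DP and 282 ± 135 CPM in DN.

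The NF-κB response was higher in DP with the preset correlation (adjusted p = 1.21e-06) but not with an estimated correlation (adjusted p = 0.0818), and 0 of its 15 members passed, 2 adjusted over the list alone. The same held for the immediate early response (adjusted p = 0.00391, then 0.31 with an estimated correlation), where 0 of 16 passed and 1 adjusted over the list alone. Treg core identity was higher with the preset correlation (adjusted p = 0.0277, then 0.108 with an estimated correlation), with 0 of 14 members past the test and 3 higher and 1 lower adjusted over the list alone. Dendritic cell markers were higher with the preset correlation (adjusted p = 0.0113, then 0.227 with an estimated correlation), with 0 of 7 past the test, 2 adjusted over the list alone, and summed levels of 410 ± 311 CPM in DP and 163 ± 59.7 CPM in DN. In DP 861 the sum reached 871 CPM, and without it the mean in DP was 256 CPM. The other 17 lists did not pass, with a smallest adjusted p of 0.0812. In all, 25 of 16186 genes passed the edgeR test, 7 higher and 18 lower in DP, and 1477 genes had an unadjusted p under 0.05 where 809 would by chance. DESeq2 called 147 genes (45 higher and 102 lower), limma voom 75 (45 and 30) and limma on the normalized values 28 (12 and 16). With only the groups compared edgeR called 12 (10 and 2), so the excess of lower genes depended on the method. The edgeR count was 11 without DP 869, 15 without DN 861 and 13 without the 4 libraries of lowest quality weight, where Il1rl1 (adjusted p = 0.0940) and Cxcr3 (0.0571) were not called. It was 17 without DP 943 (7 higher and 10 lower). It was 9 without DN 869 (1 higher and 8 lower), which ended the calls of Klrg1 (adjusted p = 0.0613), Il1rl1 (0.0601) and Laptm4b (0.0625).

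The comparison of SP with DN isolates CD103 among KLRG1- cells, and that of DP with SP isolates KLRG1 among CD103+ cells. Itgae was higher in SP than in DN, at 960 ± 155 CPM against 42.4 ± 23.4 CPM (SD, n = 4 each; log2 fold change 4.50 ± 0.41 SE, adjusted p = 3.26e-06). Tcf7 was lower in SP, at 27.9 ± 9.27 CPM (-2.06 ± 0.29, adjusted p = 0.00361), and so was Smc4, a condensin subunit gene (-0.98 ± 0.15, adjusted p = 0.0109). Lca5, a ciliary protein gene chosen after its values were seen, had 3 counts over the SP libraries. Its ratio of DN to SP was 120 (95% counting interval 40.7 to 584) and its ratio of DP to SP was 141 (48 to 688). Il1rl1 averaged 263 ± 66.0, 533 ± 137 and 1187 ± 166 CPM in DN, SP and DP. Neither step passed the test, with log2 fold changes of 1.02 ± 0.35 from DN to SP (adjusted p = 0.554) and 1.16 ± 0.35 from SP to DP (adjusted p = 0.643). Klrg1 was at 653 ± 67.4 CPM in DP and 30.9 ± 20.9 CPM in SP (4.40 ± 0.83), which did not pass (adjusted p = 0.0618). Other settings gave an adjusted p of 1.91e-05 to 0.372 for Klrg1, and 6 of 19 passed.

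The naive and central T cell genes were lower in SP than in DN with the preset correlation (adjusted p = 0.00804) but not with an estimated correlation (adjusted p = 0.534). Tcf7 was the 1 of 15 members past the test, and 3 passed adjusted over the list alone. The other 23 lists did not pass between SP and DN (smallest adjusted p 0.0575), though the interferon response was lower in SP with the replicate number as a block and the preset correlation (adjusted p = 0.0417, then 0.442 with an estimated correlation). Between DP and SP, 5 lists passed with the preset correlation and none with an estimated one, and 0 members of any of them passed the test over all genes. The effector and tissue Treg programme was higher in DP (adjusted p = 0.00113, then 0.171 with an estimated correlation, 0 members adjusted over the list alone). The NF-κB response (adjusted p = 0.00146, then 0.411, 0 adjusted over the list alone) and the immediate early response (adjusted p = 0.000224, then 0.349, 1 adjusted over the list alone) were higher too. Markers of CD8 T and NK cells were lower (adjusted p = 0.0157, then 0.349 with an estimated correlation, 2 adjusted over the list alone). Markers of myeloid cells were lower (adjusted p = 0.0383, then 0.836 with an estimated correlation, 0 adjusted over the list alone). Their sum averaged 236 ± 449 CPM in SP, where 1 library reached 909 CPM, and 5.13 ± 4.10 CPM in DP, and the list was not called without the 4 libraries of lowest quality weight (adjusted p = 0.116). The other 19 lists did not pass (smallest adjusted p 0.107).

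Between SP and DN 4 genes passed, 1 higher and 3 lower in SP, with 1430 at an unadjusted p under 0.05 and 46 called by DESeq2. The count was 2 without DN 869, SP 869 or SP 946, each of which ended the call of Smc4 (adjusted p = 0.0511, 0.0902 and 0.0532), and 1 without the 4 libraries of lowest quality weight, where Tcf7 (0.0619), Smc4 (0.0630) and Lca5 (0.117) were lost. With total counts as the scale Smc4 was lost too (0.0505). Between DP and SP 2 genes passed, Lca5 and Tmie, a hair cell gene listed at 0 in DP and at least 57.2-fold lower there by a floor of 3 counts over the group. There, 1222 genes had an unadjusted p under 0.05 and DESeq2 called 62. The count was 4 without DP 943, 5 without DP 946, 1 without SP 861, SP 869 or SP 943, and 0 without SP 946 (Tmie 0.0518) or the 4 libraries (Tmie 0.0810 and Lca5 0.0868). The call of Lca5 ended without DN 869, DN 946 or any SP library (up to an adjusted p of 0.161), and against DP without DP 861 or any SP library (up to 0.166).

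In the libraries with the LN tag, CD103+ and CD103- cells were compared in the same way. Il1rl1 was higher in LN_103P, at 92.9 ± 47.1 CPM against 10.3 ± 6.54 CPM in LN_103N (SD, n = 4 each; log2 fold change 3.17 ± 0.38 SE, adjusted p = 0.000237). Itgae was higher by 4.87 ± 0.42 on the log2 scale (763 ± 324 against 26.1 ± 13.0 CPM, adjusted p = 1.02e-06). Il18r1, which encodes a chain of the IL-18 receptor, was higher by 1.42 ± 0.25 (124 ± 29.1 against 46.6 ± 17.0 CPM, adjusted p = 0.0285). Gp49a, an immunoglobulin-like receptor gene with the close paralog Lilrb4, was higher by 3.05 ± 0.48. The remaining 3 called genes were chosen after their values were seen. Plcd1, a phospholipase C gene, was higher by 6.69 ± 1.02, and Pcsk1, a prohormone convertase gene, had 3 counts in LN_103N and a ratio of 84.8 (counting interval 28.7 to 414). Cib2 was listed at 0 in LN_103N and was at least 39.2-fold higher in LN_103P. Klrg1 was at 49.1 ± 67.8 CPM in LN_103P, where 1 library reached 151 CPM, and at 4.04 ± 2.71 CPM in LN_103N (adjusted p = 0.193). Foxp3 was at 343 ± 52.1 and 281 ± 32.4 CPM (adjusted p = 0.984).

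With the preset correlation, 6 lists were higher and 2 lower in LN_103P, and none of these calls held with an estimated correlation when all libraries were used. Without the 4 libraries of lowest quality weight 2 held with it, Treg core identity (adjusted p = 0.0454) and chemokine receptors and adhesion (adjusted p = 0.0478). Chemokine receptors and adhesion were higher (adjusted p = 0.000219, then 0.0522 with an estimated correlation), with 0 of 21 members past the test and 3 adjusted over the list alone. Treg core identity was higher (adjusted p = 0.0020, then 0.0522), with 0 of 14 members past the test and 3 adjusted over the list alone. The effector and tissue Treg programme was higher (adjusted p = 0.0020, then 0.0676), with 1 of 16 past the test, Il1rl1, and 4 higher and 2 lower adjusted over the list alone. IL-33 and IL-1 family signalling was higher (adjusted p = 0.0163, then 0.0681), with 2 of 13 past the test, Il1rl1 and Il18r1, and 2 adjusted over the list alone. Suppressive effector molecules were higher (adjusted p = 0.0118, then 0.0676), with 0 of 11 past the test and 2 adjusted over the list alone. Dendritic cell markers were higher (adjusted p = 0.00665, then 0.153), with 0 of 7 past the test, 1 adjusted over the list alone, and summed levels of 164 ± 27.6 CPM in LN_103P and 97.6 ± 37.6 CPM in LN_103N. Naive and central T cell genes were lower (adjusted p = 0.000208, then 0.0676), with 0 of 15 past the test and 0 adjusted over the list alone. Glycolysis was lower (adjusted p = 0.0302, then 0.356), with 0 of 16 past the test and 1 adjusted over the list alone. Summed myeloid markers reached 1719 CPM in 1 LN_103P library. The other 16 lists did not pass (smallest adjusted p 0.0824). Among them, summed markers of epithelial and tumour cells were at 40.1 ± 10.6 CPM in LN_103P and 10.7 ± 5.92 CPM in LN_103N (adjusted p of the list 0.0824), those of B cells at 45.4 ± 6.71 and 19.2 ± 10.96 CPM (adjusted p = 0.472), and the 4 libraries of LN_103P lay above all 4 of LN_103N on both sums. Those of CD8 T and NK cells were at 80.2 ± 24.0 and 42.3 ± 18.0 CPM (adjusted p = 0.0824) and those of stroma and endothelium at 79.98 ± 15.98 and 143 ± 53.9 CPM (adjusted p = 0.234).

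All 7 genes called by edgeR were higher in LN_103P, and 947 genes had an unadjusted p under 0.05. DESeq2 called 73 (54 higher and 19 lower), limma voom 17 (9 and 8) and limma on the normalized values 14 (10 and 4). The edgeR count was 11 without LN_103P 861 (10 and 1), 11 without the 4 libraries of lowest quality weight (7 and 4) and 1, Itgae, with only the groups compared. With limma voom the calls of Il1rl1 (adjusted p = 0.0667, within 3.08e-14 to 0.243 over the settings tried), Gp49a (0.236) and Pcsk1 (0.143) ended. Il18r1 passed in 11 of 19 settings. It was lost with only the groups compared (0.345), with the replicate number as a block (0.0721), without the 4 libraries (0.0567), and without LN_103N 861 (0.157), LN_103N 869 (0.0508), LN_103N 946 (0.0888), LN_103P 869 (0.0744) or LN_103P 946 (0.124) alone.

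Itgae, whose protein defined the sort, was the single gene called higher by edgeR in CD103+ cells both with and without the LN tag, and 0 genes were called lower in both. DESeq2 called 4 genes higher in both and 0 lower. The log2 fold changes of both CD103 comparisons had a Pearson r of 0.0325 and a Spearman rho of 0.0641 across all 16186 genes, and of 0.172 and 0.144 across the 8137 genes with a mean of at least 10 CPM. Genes are not independent replicates, so no p is given. With 4 and 7 genes called, noise in the fold changes can lower both measures. Low values thus do not show that the CD103 effects differ. The difference between both CD103 effects was tested as an interaction. The effect on Il1rl1 was 1.02 ± 0.35 without and 3.17 ± 0.38 with the LN tag, a difference of -2.15 ± 0.50 that did not pass (adjusted p = 0.472, and 0.0177 to 0.912 over other settings, of which 1 of 27 passed). No gene passed with edgeR, 1071 had an unadjusted p under 0.05, and DESeq2 called 35, limma on the normalized values 4 and limma voom 1. The count was 2 without LN_103N 946, and no list passed (smallest adjusted p 0.143).

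DN and LN_103N carried the same sort label, and their comparison asked how CD103-KLRG1- Tregs differ by the tag. Il1rl1 was higher in DN, at 263 ± 66.0 CPM against 10.3 ± 6.54 CPM (SD, n = 4 each; log2 fold change 4.67 ± 0.41 SE, adjusted p = 6.16e-08). Areg was at 348 ± 124 against 3.96 ± 2.39 CPM (6.45 ± 0.43, adjusted p = 8.35e-10). Ctla4, the coinhibitory receptor used by Tregs, was at 2759 ± 342 against 332 ± 77.5 CPM (3.06 ± 0.16, adjusted p = 1.20e-11). Gzmb, which encodes the cytotoxic protease granzyme B, had 2 counts over the LN_103N libraries and a ratio of 1380 (95% counting interval 381 to 11400). Gata1, an erythroid and megakaryocytic transcription factor gene, was lower in DN, with 3 counts there and a ratio of LN_103N to DN of 270 (92.1 to 1310). Itgae (0.70 ± 0.36, adjusted p = 0.357), Klrg1 (2.31 ± 0.78, adjusted p = 0.137) and Foxp3 (0.18 ± 0.22, adjusted p = 0.774) did not pass.

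**Figure D2:**
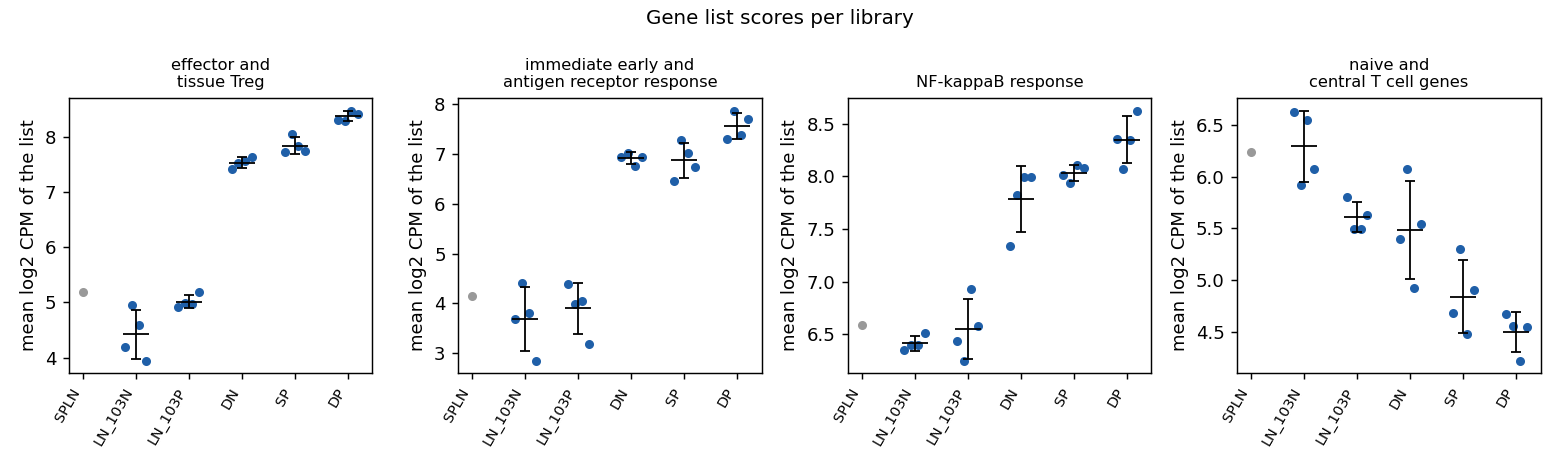
Mean log2 CPM over the members of 4 gene lists (vertical axes) in each sample, by group on the horizontal axes, with points for libraries, a grey point for the summed SPLN sample, and bars for the mean and SD of 4 libraries. On the immediate early list the 12 DN, SP and DP libraries lay between 6.45 and 7.87 and the LN_103N and LN_103P libraries between 2.85 and 4.40.

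The effector and tissue Treg programme rose as a set from LN_103N to DN (adjusted p = 1.94e-31, and 2.25e-06 with an estimated correlation). Of its 16 members 12 were higher and 0 lower, and all 16 were higher adjusted over the list alone. They included the transcription regulator genes Id2 (3.58 ± 0.28), Bhlhe40 (2.75 ± 0.23) and Gata3 (1.70 ± 0.21). Chemokine receptors and adhesion rose (adjusted p = 3.73e-14, and 0.000228 with an estimated correlation), with 10 of 21 members higher, and 15 higher and 1 lower adjusted over the list alone. Ccr8, a receptor found on skin and tumour Tregs, was at 509 ± 51.6 against 53.3 ± 13.3 CPM, and Cxcr4 was higher by 2.33 ± 0.25. Inhibitory and costimulatory receptors rose (adjusted p = 2.75e-07, and 0.0050 with an estimated correlation), with 9 of 16 higher and 2 lower, and 10 higher and 3 lower adjusted over the list alone. Pdcd1 (2.21 ± 0.21) and Icos (2.28 ± 0.23) were higher. Suppressive effector molecules rose (adjusted p = 0.000136, and 0.00680 with an estimated correlation), with 4 of 11 higher and 5 adjusted over the list alone, among them Fgl2 (3.57 ± 0.45) and Lgals1 (2.64 ± 0.40). IL-33 and IL-1 family signalling rose (adjusted p = 0.000968, and 0.0139 with an estimated correlation). It had 3 of 13 members higher, Il1rl1, Il18r1 (2.18 ± 0.26) and Il18rap (2.57 ± 0.54), and 5 adjusted over the list alone. Treg core identity did not pass as a set (adjusted p = 0.0585), though it did without the 4 libraries of lowest quality weight and with the preset correlation (adjusted p = 0.0187, then 0.0670 with an estimated correlation), with 4 of 14 members higher, Ctla4, Tnfrsf18, Tnfrsf4 and Capg, and Folr4, also known as folate receptor 4, lower (-1.97 ± 0.23).

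The immediate early and antigen receptor response rose from LN_103N to DN (adjusted p = 6.87e-24, and 0.000972 with an estimated correlation), with 12 of 16 members higher and 1 lower over all genes and adjusted over the list alone. Junb was at 4623 ± 1152 against 329 ± 51.3 CPM and Dusp1 at 1889 ± 489 against 150 ± 59.8 CPM. Atf3, a stress-response transcription factor gene, had 2 counts in LN_103N (ratio 2100, counting interval 582 to 17400). The NF-κB response rose (adjusted p = 6.45e-14, and 0.0050 with an estimated correlation), with 7 of 15 higher and 10 adjusted over the list alone. The feedback inhibitor genes Tnfaip3 (4.44 ± 0.36), Nfkbid (3.08 ± 0.25) and Nfkbia (2.35 ± 0.19) were among them. Heat shock genes passed with the preset correlation (adjusted p = 1.65e-07) but not with an estimated correlation (adjusted p = 0.0503), with 7 of 10 higher and 7 adjusted over the list alone. Hspa1a, which shares most of its sequence with Hspa1b, was higher by 4.87 ± 0.75. Fatty acid uptake and storage rose (adjusted p = 0.00187, and 0.0253 with an estimated correlation), with 2 of 12 higher, and 2 higher and 1 lower adjusted over the list alone. These were Dgat1 (3.12 ± 0.31) and Dgat2 (3.52 ± 0.79), enzymes of triglyceride synthesis. Helper T cell lineage genes rose (adjusted p = 0.00252, and 0.0140 with an estimated correlation), with 3 of 14 higher and 3 adjusted over the list alone. Those higher over all genes were Gata3 and, with larger log2 fold changes, the cytokine genes Il17a and Ifng. Il17a passed in 9 of 19 other settings and Ifng in 13 of 19.

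Markers of CD8 T and NK cells rose as a set (adjusted p = 0.000136, and 0.0204 with an estimated correlation), with 2 of 11 higher and 6 adjusted over the list alone. Their summed levels were 282 ± 135 CPM in DN and 42.3 ± 18.0 CPM in LN_103N, and the chemokine gene Ccl5 was higher by 5.13 ± 0.75. Without the 4 libraries of lowest quality weight this call was lost with an estimated correlation (adjusted p = 0.0555). Another 5 higher lists were lost with an estimated correlation when all libraries were used. Cholesterol biosynthesis (adjusted p = 0.00423, then 0.0944) had 3 of 16 members higher, the sterol regulator Insig1 (1.91 ± 0.32) among them, and 3 adjusted over the list alone. Metallothionein and oxidative stress (adjusted p = 0.00192, then 0.0561, or 0.0450 without the 4 libraries) had 2 of 10 higher and 3 adjusted over the list alone. Dendritic cell markers (adjusted p = 0.00904, then 0.122) had 2 of 7 higher and 2 adjusted over the list alone, epithelial and tumour cell markers (adjusted p = 0.0295, then 0.0561; sums of 48.7 ± 19.7 and 10.7 ± 5.92 CPM) 0 of 8 and 1, and glycolysis (adjusted p = 0.0114, then 0.197) 1 of 16 and 2. Naive and central T cell genes were lower (adjusted p = 0.00187, then 0.0759 with an estimated correlation), with 4 of 15 lower, Tcf7 (-1.26 ± 0.29) and Bcl2 (-1.46 ± 0.31) among them. In that list Il7r, the IL-7 receptor gene, was higher (1.22 ± 0.22), and 7 were lower and 1 higher adjusted over the list alone. Interferon response genes did not pass as a set (adjusted p = 0.119), with 3 of 17 lower, Stat1 among them (-1.14 ± 0.20). Markers of myeloid cells did not pass either (adjusted p = 0.0969), with 0 of 12 past the test and 8 higher adjusted over the list alone. Their sum averaged 218 ± 432 CPM in DN and 3.19 ± 2.50 CPM in LN_103N, but it reached 866 CPM in DN 946 and without that library the mean in DN was 2.26 CPM. Of the 7 lists that did not pass, Treg core identity had the smallest adjusted p.

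Between DN and LN_103N 529 genes passed, 427 higher and 102 lower in DN. DESeq2 called 958 (687 and 271) and limma voom 891 (606 and 285). The count of lower genes was 56 without LN_103N 861, 59 without LN_103N 946 and 61 without DN 943. The call of Tcf7 ended without DN 943 (adjusted p = 0.0520), that of Bcl2 without the 4 libraries of lowest quality weight (0.0584), that of Il18rap with only the groups compared (0.0847) and that of Dgat2 with only the groups compared (0.0664), with limma voom (0.0639) and with limma on the normalized values (0.0624).

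SP and LN_103P, the CD103+KLRG1- cells without and with the LN tag, were compared likewise. Il1rl1 was higher in SP, at 533 ± 137 CPM against 92.9 ± 47.1 CPM (SD, n = 4 each; log2 fold change 2.52 ± 0.37 SE, adjusted p = 9.31e-05). Areg was at 503 ± 124 against 5.06 ± 1.67 CPM (6.63 ± 0.43) and Ctla4 at 3670 ± 175 against 478 ± 21.4 CPM (2.94 ± 0.16). Nr4a1, an orphan receptor gene induced by antigen receptor signals, was at 2486 ± 500 against 74.3 ± 44.4 CPM (5.07 ± 0.41). Pparg, which encodes the transcription factor of adipose tissue Tregs, had 1 count in LN_103P (ratio 1350, counting interval 241 to 53300). Il10, the gene of a suppressive cytokine, was at 198 ± 100 against 10.2 ± 6.72 CPM (4.28 ± 1.02, adjusted p = 0.0156). Tcf7 (-2.65 ± 0.30), the lymph node homing receptor gene Sell (-2.54 ± 0.47) and Folr4 (-2.04 ± 0.23) were lower in SP, and Gata1 was listed at 0 there, at least 187-fold lower. Itgae (adjusted p = 0.688), Klrg1 (adjusted p = 0.688) and Foxp3 (adjusted p = 0.823) did not pass.

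The effector and tissue Treg programme rose from LN_103P to SP (adjusted p = 5.69e-24, and 1.30e-05 with an estimated correlation), with 12 of 16 members higher and 15 adjusted over the list alone. Bhlhe40 (3.66 ± 0.24), Ccr8 (2.95 ± 0.28) and Gata3 (1.39 ± 0.21) were among them. The immediate early response rose (adjusted p = 1.48e-17, and 0.00474 with an estimated correlation), with 12 of 16 higher and 1 lower, and 12 higher and 2 lower adjusted over the list alone, and Junb was higher by 3.49 ± 0.22. The NF-κB response rose (adjusted p = 1.14e-13, and 0.00515 with an estimated correlation), with 8 of 15 higher and 11 adjusted over the list alone, including Tnfaip3 (4.31 ± 0.36) and Nfkbiz (3.04 ± 0.26). Inhibitory and costimulatory receptors rose (adjusted p = 2.60e-07, and 0.00474 with an estimated correlation), with 9 of 16 higher and 2 lower, and 11 higher and 3 lower adjusted over the list alone. Pdcd1 (2.61 ± 0.22) and Icos (2.03 ± 0.23) were higher. Chemokine receptors and adhesion rose (adjusted p = 2.59e-07, and 0.00474 with an estimated correlation), with 10 of 21 higher and 1 lower, and 12 higher and 2 lower adjusted over the list alone, and the integrin gene Itgav was higher by 2.97 ± 0.30. Fatty acid uptake and storage rose (adjusted p = 7.64e-05, and 0.00720 with an estimated correlation), with 3 of 12 higher, Dgat1 (3.71 ± 0.31) among them, and 4 adjusted over the list alone. Suppressive effector molecules rose (adjusted p = 0.000217, and 0.00720 with an estimated correlation), with 4 of 11 higher, Il10 and Fgl2 (2.79 ± 0.44) among them, and 7 adjusted over the list alone. Helper T cell lineage genes rose (adjusted p = 0.00149, and 0.00874 with an estimated correlation), with 4 of 14 higher and 7 adjusted over the list alone. Gata3 and the cytokine genes Il17a and Ifng were among the 4, the cytokine genes with larger log2 fold changes. Il17a passed in 19 of 19 other settings and Ifng in 18 of 19.

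Another 8 lists passed between SP and LN_103P with the preset correlation and were lost with an estimated one. Heat shock (adjusted p = 3.55e-07, then 0.0601) had 6 of 10 members higher in SP and 7 adjusted over the list alone. Cholesterol biosynthesis (adjusted p = 0.000798, then 0.0601) had 3 of 16 higher and 3 adjusted over the list alone. Metallothionein and oxidative stress (adjusted p = 0.0040, then 0.0748, or 0.0317 without the 4 libraries of lowest quality weight) had 2 of 10 higher and 4 adjusted over the list alone. IL-33 and IL-1 family signalling (adjusted p = 0.0102, then 0.0522) had 3 of 13 higher and 5 adjusted over the list alone. Glycolysis (adjusted p = 0.0129, then 0.240) had 2 of 16 higher and 3 adjusted over the list alone. Dendritic cell markers (adjusted p = 0.0249, then 0.228) had 1 of 7 higher and 1 adjusted over the list alone, with summed levels of 295 ± 60.02 CPM in SP and 164 ± 27.6 CPM in LN_103P. Naive and central T cell genes were lower (adjusted p = 0.00623, then 0.132), with 5 of 15 lower and 1 higher, and 5 lower and 2 higher adjusted over the list alone. Interferon response was lower (adjusted p = 0.00928, then 0.243), with 2 of 17 lower, Stat1 among them (-1.21 ± 0.20), and 4 adjusted over the list alone. Its mean log2 CPM was 5.701 in LN_103P 946 and 3.679 to 4.096 in the other LN_103P libraries. The interferon call ended without the 4 libraries of lowest quality weight (adjusted p = 0.0658). The smallest adjusted p of the other 8 lists, which did not pass, was 0.119 for the markers of CD8 T and NK cells. Their sum was at 200 ± 44.7 CPM in SP and 80.2 ± 24.0 CPM in LN_103P, with all 4 SP libraries above all 4 of LN_103P. Treg core identity was also among the 8, with 5 of 14 members higher and 2 lower.

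Between SP and LN_103P 620 genes passed, 443 higher and 177 lower in SP. DESeq2 called 1125 (717 and 408), limma voom 988 (666 and 322) and edgeR with total counts as the scale 552 (345 and 207). The count of lower genes was 109 without LN_103P 946 and 111 without LN_103P 861. The call of Il10 ended without LN_103P 861 (adjusted p = 0.0501) or LN_103P 943 (0.0552), with limma voom (0.0795) and with limma on the normalized values (0.0885). Both tag comparisons shared 315 genes called higher and 54 called lower without the tag, where 11.7 and 1.12 would be expected of independent lists. Their log2 fold changes had a Pearson r of 0.768 and a Spearman rho of 0.627 across the 8137 genes with a mean of at least 10 CPM.

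SPLN and LN_103N shared the CD103-KLRG1- sort label, and SPLN was compared with LN_103N as 1 summed sample assumed to vary like the other groups. Small unadjusted p-values were fewer than chance gives, so the assumed spread may be too wide for SPLN. A lack of calls therefore does not show that SPLN resembles LN_103N. Itgae was at 184 CPM in SPLN and 26.1 ± 13.0 CPM in LN_103N (SD, n = 4; log2 fold change 2.82 ± 0.50 SE). Klrg1 was at 44.9 against 4.04 ± 2.71 CPM and Il1rl1 at 40.1 against 10.3 ± 6.54 CPM. The SPLN value lay above all 4 LN_103N libraries for each of these genes, although both groups carried the CD103-KLRG1- label. None passed the test, with an adjusted p of 0.151 for Itgae (0.00316 to 0.9999 over other settings, of which 5 of 19 passed) and of 1 for Klrg1 and Il1rl1. SPLN had no spread of its own, so its list tests rest on the spread of the other groups, and none of the 7 calls below held with an estimated correlation. The interferon response averaged a log2 CPM of 4.712 in SPLN and 4.716, 3.889, 3.826 and 6.015 in LN_103N 861, 869, 943 and 946. Its lower call below thus leans on LN_103N 946, and it ended without the 4 libraries of lowest quality weight. With the preset correlation the effector and tissue Treg programme was higher in SPLN (adjusted p = 0.000564, then 0.0654 with an estimated correlation), as were chemokine receptors (adjusted p = 0.0172, then 0.206), metallothionein and oxidative stress (adjusted p = 0.0325, then 0.263) and markers of CD8 T and NK cells (adjusted p = 0.0323, then 0.263). Heat shock (adjusted p = 4.44e-12, then 0.0654), naive and central T cell genes (adjusted p = 0.0323, then 0.287) and interferon response (adjusted p = 0.0323, then 0.422) were called lower, relative to all other genes. On mean log2 CPM heat shock lay below every LN_103N library, at 6.146 against 6.757 to 7.482. The naive and central T cell score (6.23) lay within the LN_103N range (5.92 to 6.62). The interferon score lay above those of LN_103N 869 and 943, so it was not lower as such. Metallothionein and oxidative stress and the CD8 T and NK markers were not called with the replicate number as a block (adjusted p = 0.126 each). Of these 7 lists, adjusted over the list alone, the first had 2 members past the test, chemokine receptors 1, the CD8 T and NK markers 1 and the others 0. The other 17 lists did not pass (smallest adjusted p 0.0734). No gene passed with edgeR, 175 had an unadjusted p under 0.05 where 809 would by chance, and DESeq2 called 13, limma voom 2 and limma on the normalized values 575.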

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

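Within each group of 4 libraries, a measure was examined when its highest or lowest library stood apart from the rest by more than Dixon's 95% critical value. Chance alone puts about 1 in 20 groups there. Of 15 library measures 4 stood apart (0.75 expected by chance), of 120 list scores 10 did (6 expected), and of 328 levels of named genes 27 did (16.4 expected). No technical or biological explanation was tested for these.

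Among library measures, DN 861 had 12075 genes seen against 13538 to 13682 in the other DN libraries, and DP 943 had 14329 against 12824 to 13052. Rn45s took 10.65% of counts in SP 869 against 27.66 to 28.01%, and 17.71% in LN_103P 946 against 29.01 to 30.52%.

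Among list scores, in mean log2 CPM, the markers of myeloid cells were at 3.69 in DN 946 against -2.514 to -1.968 in the other DN libraries, and markers of B cells at 1.367 in the same library against -1.207 to -0.9395. Metallothionein and oxidative stress was at 2.127 in DN 861 and -0.4646 in LN_103N 946. The inhibitory and costimulatory receptors were at 7.163 and the markers of epithelial and tumour cells at -0.409 in SP 943. Treg core identity was at 8.174 in DP 943. LN_103N 946 was at 2.581 on fatty acid uptake and storage and at -0.977 on markers of CD8 T and NK cells. Heat shock was at 7.448 in LN_103P 943 against 6.472 to 6.623.

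Among named genes, levels in CPM stood apart in single DN libraries for Klrg1 (49.24 in 861), Cd69 (514.8 in 861), Sc5d (133.5 in 861), Capn3 (6.722 in 946), Ccr1 (49.01 in 946), Klra8 (30.72 in 946) and Ly6c2 (51.65 in 946, against 2.875 to 3.088). In SP they did for Lyz1 (109.7 in 861), Clec7a (23.05 in 861), Siglech (3.439 in 861), Atf3 (62.03 in 861), Mt1 (38.42 in 869), Cd8a (54.16 in 943), Itgae (1191 in 946) and Klrb1c (11.74 in 946). In DP they did for H2-Aa (122.8 in 861), Cd8a (3.429 in 861) and Arl5a (298 in 943). In LN_103N they did for Ctla4 (447.7), Folr4 (1100), Nfkbid (120.6) and H2-Eb1 (8.33), all in 869. In LN_103P they did for Klrg1 (150.7 in 861, against 12.64 to 18.53), Dnajb1 (199.8 in 943), Gata3 (338.7 in 943), Itgae (1246 in 946) and Pdcd1 (181 in 946).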

How the results depend on the processing

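Removing Rn45s and leaving out the 4 libraries of lowest quality weight were chosen after seeing the data, and the other alternatives before. The cause of the differences was not tested, except that fits with fewer libraries or genes hold fewer samples or tests. Itgae kept its direction and its call under all 19 alternatives in DP versus DN, SP versus DN and LN_103P versus LN_103N, and Il1rl1 in DN versus LN_103N and SP versus LN_103P. A 2-fold change was recovered for 16% of simulated genes in DP versus DN, so that small changes were mostly not detectable.

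Counts of called genes moved as follows. With DESeq2 they were 147 for DP versus DN, 46 for SP versus DN, 62 for DP versus SP, 73 for LN_103P versus LN_103N, 958 for DN versus LN_103N, 1125 for SP versus LN_103P, 13 for SPLN versus LN_103N, 35 for the interaction and 4 shared by both CD103 comparisons. With limma voom they were, for the first 8 in that order, 75, 7, 12, 17, 891, 988, 2 and 1. With only the groups compared they were 12, 1, 1 and 1 for the first 4. In LN_103P versus LN_103N every call but that of Itgae ended there (adjusted p = 0.243 for Il1rl1, 0.715 for Gp49a and 0.345 for Il18r1, Cib2, Pcsk1 and Plcd1), as did those of Tcf7 (0.258), Smc4 and Lca5 (0.319 each) in SP versus DN and of Lca5 and Tmie (0.341 each) in DP versus SP. In DP versus DN 7 of the 25 genes were still called, and the calls lost included Cd9 (0.0512), Il10ra (0.0517), Nav2 (0.0646), S1pr1 (0.0975), Evl (0.115), Prg4 (0.135), Ly6c2 (0.146) and Slfn1 (0.176). Without the 4 libraries of lowest quality weight they were 13, 1, 0 and 11 for the first 4. With limma on the normalized signal they were 9 for SP versus DN, 8 for DP versus SP, 14 for LN_103P versus LN_103N, 575 for SPLN versus LN_103N and 4 for the interaction. With no filter they were 6 for DP versus SP, 12 for LN_103P versus LN_103N and 1 for SPLN versus LN_103N, and with the stricter filter 6 for DP versus SP. SPLN libraries entered as separate samples gave 6. As a hint from the data and not the design, 10 of 20 libraries were closest to a library of their own number in another group, where 5 would be by chance, and the mean residual correlation was higher within numbers than between them in all 10 pairs of groups. With the replicate block on the number they were 4 for DP versus SP, 1 for SPLN versus LN_103N and 1 for the interaction, and 24, 4, 7, 544 and 632 for DP versus DN, SP versus DN, LN_103P versus LN_103N, DN versus LN_103N and SP versus LN_103P. Leaving out 1 library at a time gave 9 to 25, 2 to 4, 0 to 5, 6 to 11, 380 to 491, 450 to 516 and 0 to 0 for the first 7, 0 to 2 for the interaction and 1 to 1 for the shared calls.

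No gene named as called changed direction. Among genes not called, log2 fold changes of Foxp3 changed sign in DP versus DN without the 4 libraries of lowest quality weight (-0.00334), in DP versus SP without DP 946 (0.0474) or SP 946 (0.0319), in SP versus LN_103P with total counts (-0.0165), and in the interaction with limma on the normalized signal (0.0646) and without DN 869 (0.110), DN 943 (0.0876), LN_103N 946 (0.00219) or LN_103P 946 (0.0613). With 1 library left out these values ranged from -0.0673 to 0.0474 in DP versus SP and from -0.276 to 0.110 in the interaction. Lyz1 did in DP versus SP without SP 861 (1.11, range -11.52 to 1.11), and Klrg1 in SP versus LN_103P with limma voom (0.0525), limma on the normalized signal (0.0215) and without LN_103P 861 (1.02, range -1.20 to 1.02). Over 1997 values of named genes with 1 library left out, 1836 kept their direction and side of the threshold, 143 fell short of it, 10 newly passed and 8 changed sign. Of 192 list tests, 152 kept their side with an estimated correlation and 40 fell short, and 189 did with the block. Without the 4 libraries of lowest quality weight 181 did, 3 newly passed with the preset correlation but not with an estimated one (Treg core identity in DN versus LN_103N, adjusted p = 0.0187, then 0.0670, and in DP versus DN heat shock, 0.0447, then 0.495, and fatty acid uptake and storage, 0.0104, then 0.0644) and 8 fell short. These were interferon response in SP versus LN_103P (0.0658), myeloid markers in DP versus SP, dendritic markers in LN_103P versus LN_103N (0.0724) and DN versus LN_103N (0.0589), epithelial markers in the latter (0.0692), and in SPLN interferon response (0.822), metallothionein and oxidative stress (0.406) and CD8 T and NK markers (0.233).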

Other observations

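All tests of explanations below were chosen after the results were seen, except the count of genes that other LN_103N libraries hold and the regroupings of the samples with all genes counted.

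Further genes were called between DP and DN. Nav2 (log2 fold change 1.83 ± 0.30 SE), a cytoskeletal regulator gene, Arl5a (1.74 ± 0.32) and Il10ra (1.43 ± 0.27), a chain of the IL-10 receptor, were higher in DP. Prg4 (-4.27 ± 0.78), the gene of the lubricating proteoglycan lubricin, Evl (-2.91 ± 0.54), an actin regulator gene, Slfn1 (-1.59 ± 0.28) and S1pr1 (-1.30 ± 0.24), a receptor needed for exit from lymphoid tissue, were lower. The calls of Nav2, Arl5a, Il10ra, Prg4, Evl and S1pr1 ended without DN 869 (adjusted p = 0.0587, 0.0728, 0.0876, 0.0601, 0.0613 and 0.0613), and those of Arl5a, Il10ra, Prg4, Evl, Slfn1 and S1pr1 without DP 869 (0.0699, 0.117, 0.0933, 0.117, 0.0670 and 0.0575). Without the 4 libraries of lowest quality weight those of Arl5a, Il10ra, Prg4, Slfn1, S1pr1 and Ly6c2 ended (0.0803, 0.0815, 0.166, 0.0924, 0.105 and 0.0815), with limma voom those of Evl (0.0772) and Prg4 (0.0945), with limma on the normalized values that of Prg4 (0.110), with total counts those of Arl5a (0.0533) and S1pr1 (0.0756), and for Ly6c2 with DESeq2 size factors (0.0513) or the block (0.0576). Leaving out DP 861, DP 943, DP 946, DN 861, DN 943 or DN 946 ended at least 1 of the calls of Arl5a, Il10ra, Prg4, Evl, Slfn1 and S1pr1 each (adjusted p = 0.0540 to 0.0878). Ly6c2, which has the close paralog Ly6c1, was listed at 0 in DP and was at least 225-fold lower there, with 51.65 CPM in DN 946 and 2.875 to 3.088 CPM in the other DN libraries, and its call ended without DN 946 (0.227) and without DN 861, DN 869 or any DP library (0.0645 to 0.167).

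Genes with few or no counts in the libraries with the LN tag were called as well. Calca, which encodes the neuropeptide CGRP, had 2 counts in LN_103N and a ratio of DN to LN_103N of 1510 (95% counting interval 418 to 12500), and the chemokine receptor gene Ccr1 had 1 count (ratio 1350, interval 243 to 53500). Ier3, Ablim3 and Perp, a p53 target gene, were listed at 0 in LN_103N and were at least 270-, 211- and 194-fold higher in DN. Irg1, which encodes the enzyme that makes itaconate, was listed at 0 in LN_103P and was at least 283-fold higher in SP. Sgip1 (ratio 1230, 221 to 48700) and the potassium channel gene Kcna4 (715, 128 to 28300) had 1 count in LN_103P, and Spin2 had 2 in SP (ratio of LN_103P to SP 309, 85.2 to 2550). Cell cycle genes, markers of B cells, of stroma and endothelium and of red cells and platelets passed as sets in none of the 8 comparisons, with smallest adjusted p of 0.277, 0.360, 0.152 and 0.277.

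Immediate early and NF-κB genes were higher in the DN, SP and DP libraries, which carry no tag, than in those with the LN tag. Heat shock genes were too with the preset correlation, while with an estimated correlation the set was not called (adjusted p = 0.0503 in DN and 0.0601 in SP). The summed SPLN sample lay within the range of the LN libraries on the immediate early (4.15) and NF-κB (6.59) scores. On the heat shock score (6.146) it lay below all of them. Scaling was argued against, since of 52 calls of list members 46 (88.5%) were kept with total counts as the scale and 52 without Rn45s. Handling of the tissue during cell isolation cannot be told apart from the tag. All 12 DN, SP and DP libraries lay above every LN library on the immediate early score, and the labels give no handling that crosses the tag. RNA from other cells stays open too. On the CD8 T and NK markers 10 of these 12 libraries lay above every LN library, on the dendritic markers 9 and on the epithelial markers 6. The number of the 12 that lay above on none of the 7 lists was 0. The most abundant CD8 T and NK markers were Ccl5 (128 CPM in DN, 3.66 in LN_103N) and Nkg7 (82.7 and 11.9). No list had all 12 above. A response of Tregs in the tissue of origin stays open as an untested hypothesis.

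Itgae and Klrg1 were higher in SPLN than in LN_103N although both carry the same sort label. Depth was argued against, since with all libraries thinned to the smallest total the lowest SPLN library had 1631 Itgae counts against at most 360 in LN_103N. A mixed sample holding CD103+KLRG1- cells may account for part of it. The share of such cells computed from each of the 7 genes called in LN_103P was 21.4% by Itgae, 36.1% by Il1rl1, 15.7% by Il18r1 and 13.4% by Pcsk1. It differed by over 2-fold from that of Itgae for 3 of the 7 genes, Cib2 (52.6%), Plcd1 (57.0%) and Gp49a (99.1%, and 88.9 to 130% with 1 LN library left out), and Klrg1 gave 90.7%. The value for Klrg1 rests on LN_103P 861, without which it was 364%, more than such cells could supply. The count of 3 genes lies between the bounds set for both outcomes, and it turns on single libraries. Without LN_103N 946 Il18r1 gave 8.3% against 21.8% by Itgae, and without LN_103P 861 Il1rl1 gave 47.9% against 20.1%. Each adds a gene that differs by over 2-fold, while without LN_103P 946 Plcd1 (52.3%) came within 2-fold of Itgae (27.4%). Cib2 and Pcsk1 were at only 1.25 and 0.70 CPM in SPLN. A mixed sample thus stays open, as does a difference of origin behind the tags, which was not tested.

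More genes were seen in the SPLN libraries than in the others. Depth was argued against, since after thinning the lowest SPLN library held 15945 genes and the highest other library 14291. Fewer distinct RNA molecules in the other libraries may contribute. Other LN_103N libraries held 48.8 to 59.5% of the genes seen in SPLN library 1 and missed by a given LN_103N library. That range straddles the bound set beforehand, and SPLN library 1 was the only SPLN library used, so the test did not decide it. RNA from other cells stays open too, since the summed markers in SPLN lay above every LN_103N library for 2 of 7 lists, those of CD8 T and NK cells (83.02 CPM) and of epithelial and tumour cells (34.23 CPM). A difference of tissue was not tested.

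Regrouping the libraries tested whether chance could give as many calls. Of the 35 splits of 8 libraries, 1, the real one, gave as many for DP versus DN (25, highest other 2). The same held for SP versus DN (4, highest other 1) and LN_103P versus LN_103N (7, highest other 3). It also held for DN versus LN_103N (529, highest other 11) and SP versus LN_103P (620, highest other 2). This argues against chance there but does not exclude it. A result of 1 is the smallest this count can give, and it was not adjusted over the comparisons. Mixed splits also put group differences into the spread, which lowers their counts. Libraries were moved without regard to the numbers in the titles, so the splits are too free if these mark animals. Itgae and Klrg1, fixed by the sort, did not decide the result. Without them 1 of 35 splits, the real one, still gave as many for DP versus DN (23, highest other 2). So it did for SP versus DN (3, highest other 1) and LN_103P versus LN_103N (6, highest other 3). The splits were fitted with all groups and libraries. With only the groups compared, where no splits were run, Itgae alone was called for SP versus DN and for LN_103P versus LN_103N. It alone was also called for SP versus DN without the 4 libraries of lowest quality weight. The argument against chance does not extend to those fits. Chance cannot be excluded for the 2 calls of DP versus SP, which 2 of 35 splits reached. For the interaction, all 100 splits drawn gave at least its 0 calls (highest other 3), as any split must, so this says nothing. For the gene shared by both CD103 comparisons, 1 of 100 splits, the real one, gave 1 (highest other 0), but this is Itgae, whose sharing the sort fixed, so this says nothing about chance either.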
